A study of Mus musculus with 4 samples.

How the data were processed

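RNA from mouse liver was sequenced on a HiSeq 2000 from TruSeq libraries, 2 of wild type and 2 of hemojuvelin knockout animals, all fed the same low iron diet. The submitters' processing notes name FastQC, TopHat and Cufflinks without versions, and the build mm9. The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) with lower and upper confidence bounds, also in FPKM, by the authors from Cufflinks. The files hold loci that Cufflinks assembled in each library on its own, with coordinates and no gene names, so neither loci nor genes are matched between libraries as deposited.

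The coordinates fit build GRCm38 and not mm9. The last locus on chromosome Y in wild type replicate 1 ends at base 90767996. Of loci over 2000 bases, 13.5% to 33.2% had their start or end within 20 bases of a gene start or end of GENCODE mouse release M21. After a shift of the loci along the chromosome the share was 0.219% to 0.336%, and gene positions on mm9 were not tried. No locus lies on the mitochondrial genome. The FPKM of short loci lie far above their own confidence bounds, up to 1.30e+08, as the values themselves show. Depth was taken from the step between the confidence bounds of short loci, with a step assumed to be 1 fragment. The step chosen was the largest that left nearly all bounds whole multiples of it, within 0.05 for more than 99.8% of bounds. That share follows from the choice and is no separate check. The step gave 87.0, 51.3, 55.0 and 132 M fragments in wild type replicates 1 and 2 and knockout replicates 1 and 2. Knockout replicate 1 was the most fragmented, with 2.15 loci per gene and 38.5% of loci at 150 to 250 bases, and knockout replicate 2 the least, with 1.48 loci per gene.

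Loci were assigned to the 21761 protein-coding genes by position, after predicted models sharing at least 25% of their exonic bases with a named gene were left out. A locus went to the gene with most of its exonic bases if at least 50% of it lay inside that gene, and was left out where a second gene held more than 25% as many of its bases. A locus within 1 exon had to be at least 50% exonic, and a locus with an FPKM over 3 times the midpoint of its bounds was left out. A gene's value was the mean FPKM of its loci weighted by exonic bases, and was used if the loci spanned at least 50% of a coding transcript. The plan had been to sum entries of 1 gene symbol, which the files do not allow, since they carry no symbols and densities of pieces of a transcript cannot be added. The weighted mean was chosen after the data were seen, from the spread of the wild type pair, whose log2 differences had an SD of 0.421, against 0.556 for the highest locus, 0.721 for the sum and 0.789 for the midpoint of the bounds. The SD of the knockout pair was 0.645 with the weighted mean. The choice did not use differences between the genotypes, and the limits on position, span and inflation were likewise set after the data were seen.

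Of these genes 11502 had a value in any library, and 7940 in all 4. Values were scaled by the median of ratios to the geometric mean library, with factors of 0.939 and 0.917 for the wild type libraries and 1.19 and 0.958 for the knockout libraries. Genes with at least 1 FPKM in at least 2 libraries were kept, which left 7923. Knockout was compared with wild type on log2(scaled FPKM + 1) by limma 3.58.1 in R 4.3.3, two-sided, with a mean-variance trend, 2 residual and 2.93 prior degrees of freedom, and Benjamini-Hochberg adjustment over all genes tested with a threshold of 0.05. With 2 libraries against 2, an exact permutation test of a single gene cannot give a p under 0.333. Scaled FPKM are given per library or as mean ± SD, and log2 differences are knockout minus wild type.

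The 39 gene lists, the test, the filter, the named genes and most alternatives were fixed before the data were examined. Lists with at least 4 tested members, 27 of them, were tested by camera with a preset correlation of 0.01, and also with an estimated correlation and by fry. The rule for named genes took Hjv, a fixed set of iron and BMP genes, the genes past the adjusted threshold filled up to 8 per direction by smallest unadjusted p among genes with a 2-fold difference, groups that did not overlap and a mean of at least 2 scaled FPKM in the higher group, and up to 4 leading members of each list called. The values of 1 member of the interferon list are not reported or drawn here, although the list's tests include it. Other list members, genes seen in 1 genotype, and genes named for their position were chosen after their values were seen.

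The alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, the deposited scale, quantile normalization, limma without a trend, with robust moderation and with the replicate number as a block, the highest locus per gene, all loci whatever their status, absent genes set to 0, each library left out, and camera and fry as above. Added after the data were seen were the sum of loci, the midpoint of the bounds, spans of at least 80% or of any size, loci up to 1.5 times the midpoint, and a correction for GC content and transcript length in each library. The labels give no batch, lane or date.

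The assignment of loci was tested on simulated data, where 1892 of 2000 genes received a value and 100% of those values lay within 1% of the truth. All simulated pieces of a gene had the same FPKM, without inflated values, so their weighted mean returned that FPKM by design. The simulation therefore tested which gene a locus went to, and not the values from unequal or inflated pieces. The gene test was tested on simulated changes of 1, 2 and 4 on the log2 scale in the layout of these libraries, and called 1.49%, 70.1% and 92.4% of the changed genes at the adjusted threshold, with 8 unchanged genes called. A shift of -1 in 16 members of a list was called by camera in 50 of 50 draws. The changed genes of the gene test were drawn from the more abundant ones. In both simulations genes varied independently of each other and equally in both genotypes, which suits camera's preset correlation. The draws therefore do not show how camera behaves where genes are correlated or the knockout pair varies more. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 prepared the tables, and matplotlib 3.10.9 the figures.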

Results

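Liver RNA was sequenced from male C57BL/6 mice, 2 libraries from wild type animals and 2 from animals homozygous for a disrupted hemojuvelin gene (Hjv, named Hfe2 in older annotations). All were fed the AIN-93G low iron diet with 2.5 mg of iron per kg from 5 weeks of age for 50 days, and the tissue was taken at 12 weeks. If a step between confidence bounds is 1 fragment, the libraries hold 87.0 and 51.3 M fragments in wild type replicates 1 and 2. On the same assumption they hold 55.0 and 132 M in knockout replicates 1 and 2. Transcripts were assembled separately in each library, into 41541 and 26238 loci in the wild type libraries and 56237 and 30190 loci in the knockout libraries. The labels do not say that each library comes from a separate animal, so the spread and the p-values measure differences between these libraries. A gene with no assembled locus is not a gene at 0, since albumin (Alb) had no locus in any of the 4 libraries.

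The first comparison concerned the targeted gene and hepcidin, the hormone that hemojuvelin induces in hepatocytes as a co-receptor for bone morphogenetic proteins (BMPs). Hjv (chromosome 3, 96525172 to 96529210, GRCm38) was assembled at 9.18 and 29.6 scaled FPKM in the wild type libraries. It had no locus in knockout replicate 1, and 0.236 scaled FPKM over 14.3% of the transcript in knockout replicate 2. Another locus that touched its exons in knockout replicate 2 was not used. Hepcidin (Hamp, chromosome 7, 30942368 to 30944032) measured 21.9 and 100 in the wild type libraries, had no locus in knockout replicate 1 and measured 1.61 in knockout replicate 2. Its close paralog Hamp2 (chromosome 7, 30922372 to 30924681) measured 15.9 and 59.5, had only a short unused locus in knockout replicate 1 and measured 3.32 in knockout replicate 2.

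Against the mean of the wild type libraries, knockout replicate 2 differed by a log2 value of -3.84 for Hjv, -4.20 for Hamp and -2.89 for Hamp2. The SD between the wild type libraries was 1.12 for Hjv, 1.52 for Hamp and 1.30 for Hamp2 on the same scale, and 1 knockout library gives no spread for its own group. Taking 1 wild type library at a time, the difference was -5.30 without wild type replicate 1 and -3.15 without wild type replicate 2 for Hamp, and -3.83 and -1.98 for Hamp2. The loci spanned 45.1% of the Hjv transcript in wild type replicate 1 and 81.5% in wild type replicate 2. These values were taken whatever the share of the transcript spanned, and no test was made, since no value could be taken from knockout replicate 1. The deposited value of a transcript as short as Hamp lies above its own confidence bounds, at 91.8 FPKM with bounds of 41.8 and 50.9 in wild type replicate 2.

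**Figure D1:**
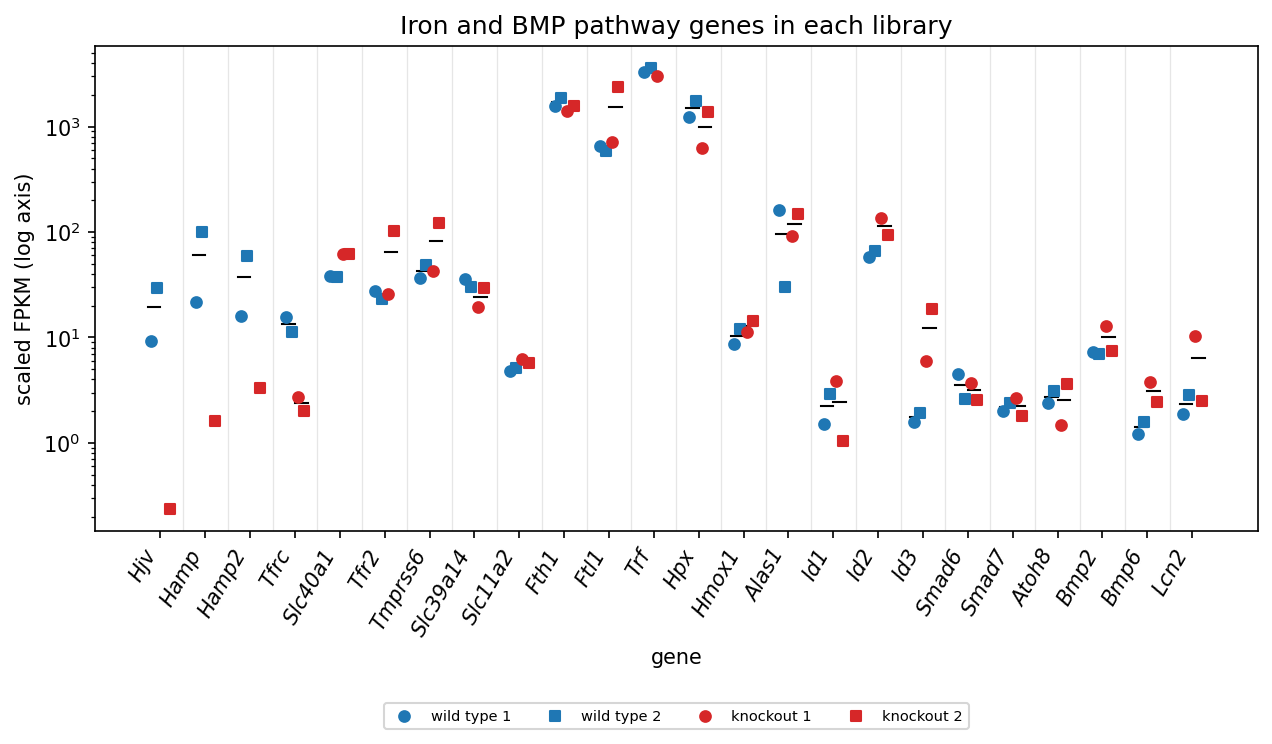
Scaled FPKM on a log axis for the genes of iron handling and BMP signaling, 1 point per library, with a short bar at the mean of a group where both of its libraries have a value. Hjv, Hamp and Hamp2 have no value in knockout replicate 1, and lie at 0.236, 1.61 and 3.32 in knockout replicate 2.

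The comparison of knockout with wild type over all genes asked what else loss of hemojuvelin changes in the liver on this diet. The genes with the strongest evidence of a lower level included Acly, which makes cytosolic acetyl-CoA for lipid synthesis, at 205 ± 8.96 scaled FPKM in wild type and 37.0 ± 5.62 in knockout (SD, n = 2 each). Me1, the cytosolic malic enzyme that supplies NADPH, measured 176 ± 15.1 in wild type and 58.3 ± 1.73 in knockout (SD, n = 2 each). The transferrin receptor Tfrc, which takes up transferrin-bound iron and whose mRNA is degraded when cell iron is plentiful, measured 13.4 ± 2.98 in wild type and 2.39 ± 0.514 in knockout (SD, n = 2 each). Among genes higher in knockout, the cytochrome P450 gene Cyp2c39 measured 1.24 ± 0.604 in wild type and 92.3 ± 33.3 in knockout (SD, n = 2 each), a ratio of 74.4. None of these single genes passed the test over all genes.

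By limma, 0 genes were higher and 0 lower at an adjusted p under 0.05 among the 7923 genes tested, and the smallest adjusted p was 0.162. At an unadjusted p under 0.05, 475 genes were higher and 396 lower, 871 together. These counts moved with the libraries used and with the scaling, at 861 higher and 139 lower for values as deposited. Cyp2c39 had a log2 difference of 5.36 with an SE of 0.34 and an adjusted p of 0.162. Acly had a log2 difference of -2.45 with an SE of 0.20, and Sugct, a CoA transferase of glutarate metabolism, -2.61 with an SE of 0.21, each at an adjusted p of 0.162. The other genes higher in both knockout libraries by this rule were Sap30l (log2 difference 1.95), a subunit of histone deacetylase complexes, Tmem51 (2.02), Apcs (1.71), the serum amyloid P component, Oaf (2.82), Sae1 (1.42), a subunit of the SUMO activating enzyme, Ildr2 (1.73) and Aldh2 (1.66), the mitochondrial aldehyde dehydrogenase. The other genes lower in both were the fatty acid binding protein Fabp4 (log2 difference -2.85), Ugt3a1 (-1.75), Dusp1 (-2.50), a phosphatase of MAP kinases, the steroid dehydrogenase Hsd3b5 (-1.98), Me1 (-1.58) and Tfrc (-2.08).

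Of the tested genes, 319 had groups that did not overlap and a difference of at least 2-fold, 212 higher and 107 lower in knockout. Groups that did not overlap made up 45.9% of the genes, against 29.7% with replicates 2 against replicates 1. The share was 24.4% with wild type replicate 2 and knockout replicate 1 against the others. Chance gives 33.3% on average with 2 libraries against 2. A gene separates at most 1 of the 3 splits, so the shares are tied and 1 of them nearly always exceeds 33.3%. The other splits of the 4 libraries gave 124 and 77 genes with a 2-fold difference, 195 and 134 genes at an unadjusted p under 0.05, and 0 past the adjusted threshold, and each of them gave 1 list called by camera, against 3 for the genotypes. The counts depended on the libraries used, with a lone library assumed to vary like the other group. Past the adjusted threshold, 214 genes were higher and 67 lower without knockout replicate 1, 16 and 13 without knockout replicate 2, and 0 and 1 without wild type replicate 1 or without wild type replicate 2. At an unadjusted p under 0.05, 1311 were higher and 881 lower without knockout replicate 1, 824 and 680 without knockout replicate 2, 125 and 139 without wild type replicate 1, and 166 and 129 without wild type replicate 2.

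**Figure D2:**
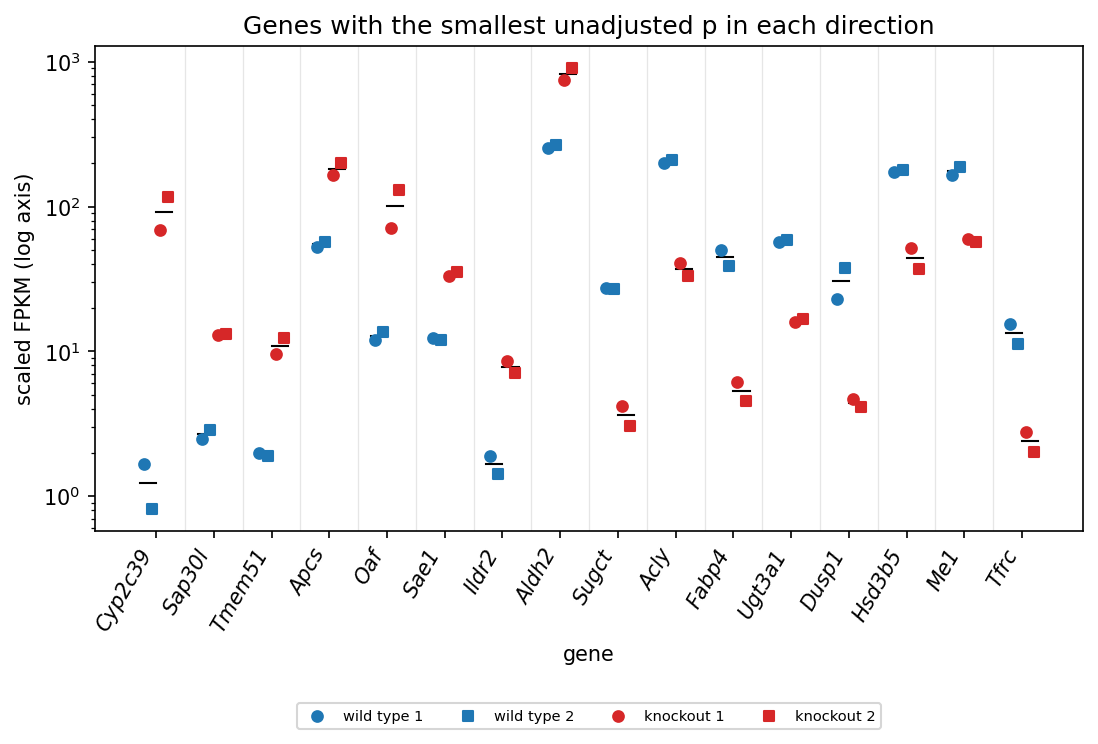
Scaled FPKM on a log axis for the 8 genes with the smallest unadjusted p in each direction among those with a 2-fold difference and groups that did not overlap. Each library has 1 point and each group a short bar at its mean. By that choice both knockout libraries lie above both wild type libraries for the first 8 genes and below them for the last 8. Cyp2c39 lies at 1.24 in wild type and 92.3 in knockout on average.

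Genes that move and store iron differed unequally between the genotypes. Tfrc was lower in both knockout libraries, and it was the 1 gene of the iron transport and storage list that passed limma when adjusted over the list alone (adjusted p = 0.00789), against an adjusted p of 0.253 over all genes. The iron exporter ferroportin (Slc40a1) measured 37.6 ± 0.543 scaled FPKM in wild type and 61.7 ± 0.362 in knockout (SD, n = 2 each), with a log2 difference of 0.70 and an adjusted p of 0.396. The ferritin heavy chain Fth1 measured 1571 and 1859 in the wild type libraries and 1416 and 1554 in the knockout libraries. The ferritin light chain Ftl1 measured 651 and 586 in wild type, 718 in knockout replicate 1 and 2372 in knockout replicate 2.

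Of the 19 tested members of this list, both knockout libraries lay above both wild type libraries for 9 and below them for 4. The list's median log2 difference was 0.23, and camera gave an adjusted p of 0.452. The iron importers Slc11a2 and Slc39a14 measured 4.94 and 33.0 on average in wild type and 5.97 and 24.4 in knockout. Slc39a14 had a log2 difference of -0.44 that turned to 0.01 with the highest locus per gene and to 0.33 with the loci of a gene summed. Transferrin (Trf) measured 3264 and 3588 in wild type and 3027 in knockout replicate 1, with no locus in knockout replicate 2. The heme scavenger hemopexin (Hpx) measured 1243 and 1755 in wild type and 630 and 1371 in knockout. Lcn2, a siderophore-binding protein, measured 1.87 and 2.85 in wild type and 10.3 and 2.48 in knockout, and was not tested because its loci spanned too little of the transcript in 1 library.

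The heme synthesis and breakdown list had a median log2 difference of 0.36 over 10 tested members, with 4 above in both knockout libraries and 0 below. Camera gave it an adjusted p of 0.0599, and 0.0230 under quantile normalization with a median of 0.35 (range 0.00430 to 0.650 over the alternatives), so its call depends on the setting. With an estimated correlation it was not called (adjusted p = 0.650 with an estimated correlation). Blvrb, a biliverdin reductase, measured 25.8 and 21.1 in wild type and 48.4 and 44.9 in knockout, and passed when adjusted over the list alone (adjusted p = 0.0450). Alad, which makes porphobilinogen, measured 7.35 and 6.93 in wild type and 16.4 and 85.7 in knockout. Heme oxygenase 1 (Hmox1) measured 10.3 in wild type and 12.8 in knockout on average. Alas1, the rate-limiting enzyme of hepatic heme synthesis, measured 163 and 29.9 in wild type and 91.9 and 148 in knockout, and its log2 difference of 0.72 became -0.49 without wild type replicate 2.

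Of the 11 BMP/SMAD target genes listed 3 were tested, and of these 1 was above in both knockout libraries and 2 overlapped. Id2, an inhibitor of DNA binding induced by BMPs, measured 58.0 and 65.4 in wild type and 135 and 94.1 in knockout, with a log2 difference of 0.86 and an adjusted p of 0.410. Smad7, which inhibits BMP signaling, measured 2.01 and 2.37 in wild type and 2.67 and 1.80 in knockout. Its log2 difference of 0.01 became -0.15 under quantile normalization, so it has no direction here. Id1, Id3, Smad6 and Atoh8 were not tested because less than 50% of their transcripts was assembled in at least 1 library. Id1 measured 1.51 and 2.93 in wild type and 3.86 and 1.05 in knockout, Id3 1.58 and 1.94 against 5.93 and 18.5, Smad6 4.53 and 2.62 against 3.73 and 2.56, and Atoh8 2.38 and 3.10 against 1.48 and 3.60.

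Of the BMP pathway and hepcidin regulators, 3 of 15 tested members were above in both knockout libraries and 0 below, and camera gave an adjusted p of 0.252 for a median log2 difference of 0.13. The ligand Bmp2 measured 7.31 and 7.04 in wild type and 12.7 and 7.49 in knockout. Bmp6, the ligand that iron induces in sinusoidal endothelium, measured 1.21 and 1.59 in wild type and 3.79 and 2.43 in knockout, and was not tested for the same reason as Id1. Tmprss6, the protease that cleaves hemojuvelin, measured 36.5 and 48.5 in wild type, 42.6 in knockout replicate 1 and 120 in knockout replicate 2. The iron sensor Tfr2 measured 27.4 and 23.2 in wild type, 25.8 in knockout replicate 1 and 102 in knockout replicate 2. For both genes, as for Ftl1, knockout replicate 2 alone stood apart, and across genes the log2 ratio of knockout replicate 2 to knockout replicate 1 followed GC content with a Spearman correlation of 0.478.

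Genes of fatty acid synthesis were lower in the knockout libraries as a group by camera with its preset correlation (adjusted p = 9.91e-05). The call was lost with an estimated correlation (adjusted p = 0.650 with an estimated correlation) and by fry (adjusted p = 0.123). The estimated correlation was -0.0142, below the preset 0.01, so a stronger correlation was not why camera lost the call. Of 16 tested members, 10 were below in both knockout libraries, 1 was above in both and 5 overlapped, with a median log2 difference of -0.72, or -0.52 with values as deposited. Besides Acly and Me1, the elongase Elovl6 measured 48.2 ± 2.14 scaled FPKM in wild type and 12.6 ± 5.26 in knockout (SD, n = 2 each), and the desaturase Fads2 406 ± 11.2 in wild type and 205 ± 15.3 in knockout (SD, n = 2 each). Acacb, an acetyl-CoA carboxylase, had a log2 difference of -0.99, and the elongase Elovl5 -0.74. Mlxipl, the carbohydrate-responsive transcription factor ChREBP, lay the other way with a log2 difference of 1.03. Fatty acid synthase (Fasn) measured 25.1 and 24.6 in wild type and 11.6 and 23.8 in knockout. The stearoyl-CoA desaturase Scd1 had no locus in wild type replicate 1 and was not tested, with 2717 in wild type replicate 2 and 753 and 489 in the knockout libraries.

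Adjusted over the fatty acid synthesis list alone, 7 members passed limma (Acly, Me1, Elovl6, Fads2, Acacb and Elovl5 lower, Mlxipl higher), and 0 passed over all genes. Without knockout replicate 1 the list's median was -0.77 and its adjusted p 0.0628, and over the alternatives its adjusted p ranged from 7.47e-07 to 0.650.

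Male-biased liver genes, those expressed more in male than in female mouse liver, were also lower as a group in the knockout libraries by camera (adjusted p = 0.00468). The call was lost with an estimated correlation (adjusted p = 0.650 with an estimated correlation) and by fry (adjusted p = 0.123). The estimated correlation was 0.00358, below the preset 0.01, so here too a stronger correlation was not why camera lost the call. Of 10 tested members, 5 were below in both knockout libraries and 1 above, with a median log2 difference of -0.44, or -0.24 with values as deposited. Hsd3b5 measured 176 ± 3.42 scaled FPKM in wild type and 44.3 ± 9.99 in knockout (SD, n = 2 each), and C6, a component of the complement attack complex, 110 ± 11.2 in wild type and 28.7 ± 6.88 in knockout (SD, n = 2 each). The elongase Elovl3 measured 161 and 85.3 in wild type and 46.2 and 52.5 in knockout, and Nudt7, a peroxisomal hydrolase of coenzyme A, 584 and 593 against 420 and 350. The fatty acid hydroxylase Cyp4a12a measured 222 and 220 in wild type and 246 and 207 in knockout. Its near-identical neighbor Cyp4a12b measured 136 and 138 in wild type and had no locus in either knockout library. Hsd3b5 lies 2.09 Mb from Hjv.

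Adjusted over the list alone, 2 members passed (Hsd3b5 and C6), and 0 passed over all genes. The list's adjusted p was 0.0584 without knockout replicate 1, with a median of -0.62, and 0.0518 under quantile normalization, in a range of 0.000143 to 0.650 over the alternatives.

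Interferon response genes were the third list called lower by camera (adjusted p = 0.0481). The call was lost with an estimated correlation (adjusted p = 0.650 with an estimated correlation) and by fry (adjusted p = 0.341). The estimated correlation was -2.11e-05, again below the preset 0.01. Of 16 tested members, 6 were below in both knockout libraries and 0 above, with a median log2 difference of -0.18, or -0.02 with values as deposited and -0.30 under quantile normalization. The antiviral gene Ifit3 measured 8.36 ± 0.390 scaled FPKM in wild type and 3.98 ± 0.607 in knockout (SD, n = 2 each), and the interferon-induced GTPase Iigp1 126 ± 5.72 in wild type and 83.1 ± 2.50 in knockout (SD, n = 2 each). Gbp2, a guanylate-binding protein, measured 2.33 and 3.19 in wild type and 1.67 and 1.02 in knockout.

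Adjusted over the interferon list alone 0 members passed limma, and 3 had an unadjusted p under 0.05. Camera's adjusted p was 0.233 without wild type replicate 2, with a median of -0.25, and 0.109 without knockout replicate 1, with a median of -0.33. It ranged from 0.00543 to 0.650 over the alternatives.

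**Figure D3:**
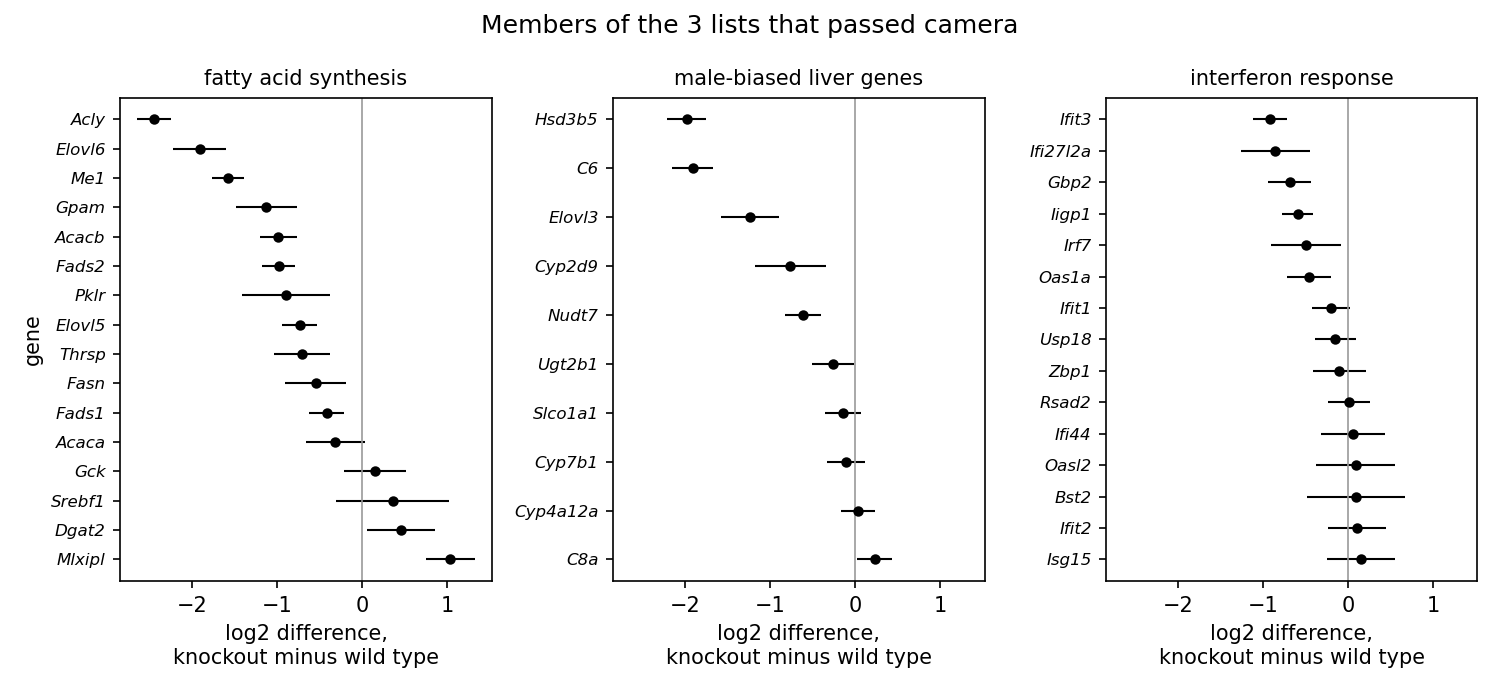
Log2 difference of knockout minus wild type for tested members of the 3 lists that passed camera, as points with the SE from limma as lines. The median member lies at -0.72 for fatty acid synthesis, -0.44 for the male-biased genes and -0.18 for the interferon response.

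The other lists tested did not pass camera in the main analysis. Of the 27 lists with at least 4 tested members, 24 had adjusted p-values from 0.0511 to 0.993, and with an estimated correlation 0 lists passed. The gluconeogenesis and fasting list had a median log2 difference of -0.44 over 9 members and an adjusted p of 0.0511. It was called lower with values as deposited (adjusted p 0.0102) and in 9 of 24 alternatives in all, with a range of 0.00283 to 0.650 (adjusted p = 0.650 with an estimated correlation). Among these, the GC and length correction added after the data were seen, gave a median of -0.65 and an adjusted p of 0.0369. Of its members Pck1, which makes phosphoenolpyruvate from oxaloacetate, measured 818 and 984 in wild type and 538 and 614 in knockout, and the tyrosine aminotransferase Tat 454 and 407 against 248 and 238. Foxo1, a transcription factor of the fasting response, had an outlying 22468 scaled FPKM in wild type replicate 1 against 11.2 in wild type replicate 2 and 7.70 and 6.67 in knockout. Fatty acid oxidation and PPARalpha targets had a median of -0.28 over 23 members and an adjusted p of 0.0768, with the lipid droplet protein Plin2 at 244 and 222 in wild type and 99.7 and 102 in knockout. The cholesterol synthesis list had a median of -0.21 over 22 members and an adjusted p of 0.181. The nuclear-encoded oxidative phosphorylation list had a median of -0.19 over 79 members and an adjusted p of 0.0599, and its median was 0.01 with the values as deposited. That scale shifts the median log2 difference of all genes to 0.19, against 0.02 after scaling.

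Calls of several lists not called in the main analysis varied with the setting. Of 24 alternatives, some of them chosen after the data were seen, 4 called the heme list and 4 the cytosolic ribosomal proteins higher, and 2 the stellate cell markers higher. The unfolded protein and stress list was called lower in 5, oxidative phosphorylation in 5, fatty acid oxidation in 2 and the Kupffer cell markers in 2. The adjusted p ranged from 0.00430 to 0.650 for heme, 0.00123 to 0.936 for ribosomal proteins, 0.0148 to 0.664 for stellate cells and 0.00264 to 0.664 for the stress list. It ranged from 0.0148 to 0.836 for oxidative phosphorylation, 0.0221 to 0.650 for fatty acid oxidation and 0.0230 to 0.958 for Kupffer cells. None of them was called with an estimated correlation.

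Markers of the liver cell types did not share 1 direction. Kupffer cell and macrophage markers had a median log2 difference of -0.25 over 14 members, with 6 below and 1 above in both knockout libraries and a camera adjusted p of 0.225. The Kupffer cell receptor Vsig4 measured 22.3 and 24.7 in wild type and 13.2 and 14.3 in knockout. Stellate cell and matrix markers had a median of 0.46 over 9 members and an adjusted p of 0.0954, with the lectin Colec11 at 11.7 and 9.44 in wild type and 18.1 and 16.9 in knockout. Sinusoidal endothelial markers had a median of 0.23 over 13 members and an adjusted p of 0.237, and hepatocyte markers a median of -0.00 over 8 members, or 0.20 with values as deposited, and an adjusted p of 0.993. Few markers of the remaining types were tested, 2 for cholangiocytes, 2 for adipocytes, and 1 each for lymphocytes, neutrophils, erythroid cells and pancreatic acinar cells, and 0 for striated muscle. The tested adipocyte markers lay in opposite directions, with Fabp4 at a log2 difference of -2.85 and Car3 at 0.70.

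Some genes were assembled in both libraries of 1 genotype and in neither of the other. With at least 2 scaled FPKM, 11 genes had loci only in the wild type libraries and 5 only in the knockout libraries, against 0 to 3 for each side of the other splits. The carboxylesterase Ces2c measured 34.3 and 36.3 and the small ubiquitin-like modifier Sumo2 39.0 and 36.0 in wild type. In the knockout libraries the aspartic protease Ctse measured 24.3 and 20.6, the asparagine synthetase Asns 7.39 and 10.5, and the metallothionein Mt1 2.55 and 21.9. Several of these genes have near-identical copies in the genome, and the lack of a locus does not show that a transcript was absent.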

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

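Tests chosen only after the result was seen are those with loci summed, the midpoint of the bounds, other spans, loci up to 1.5 times the midpoint and the GC and length correction. Of 823 values of 38 named genes under 22 alternatives, 814 kept their direction and 9 reversed. Much of this agreement was fixed in advance. Changes of the filter, the trend, the moderation or the block left the log2 differences as they were. Genes named for groups that did not overlap could hardly reverse with 1 library left out. In fits of all 4 libraries, Cyp2c39 alone of these genes passed the adjusted threshold, with values as deposited. Smad7 became -0.15 under quantile normalization, -0.0806 with the highest locus, -0.99 with loci summed and -0.37 with the GC and length correction, and ranged from -0.18 (without knockout replicate 1) to 0.20 with 1 library left out, below 0 also without wild type replicate 1 (-0.08). Slc39a14 became 0.0141 with the highest locus and 0.33 with loci summed, and Alas1 ranged from -0.49 (without wild type replicate 2) to 1.92 with 1 library left out. With values as deposited 1 gene was higher (Cyp2c39, log2 difference 5.51, adjusted p 0.00739) and 5 lists were called, and the genes at an unadjusted p under 0.05 were 861 higher and 139 lower. With absent genes set to 0, 1 gene was higher (Ctse) and 6 were lower (Cyp4a12b, Sumo2, Ces2c, Mthfsl, Zfp982 and Hmgn2), while Hamp had a log2 difference of -4.90 and an adjusted p of 0.368. The gene counts in the other alternatives that use all 4 libraries stayed at 0 by limma. Lists called numbered 6 with a filter at 5 FPKM, 6 with the highest locus, 6 with no minimum span, 0 with an estimated correlation and 0 by fry. With an estimated correlation the medians of -0.72, -0.44 and -0.18 had an adjusted p of 0.650 each, and by fry 0.123, 0.123 and 0.341 for fatty acid synthesis, male-biased genes and the interferon response. The interferon median was -0.54 with a filter at 5 FPKM (adjusted p 0.125), -0.23 with loci summed (0.251), -0.15 with loci up to 1.5 times the midpoint (0.0598) and -0.13 with the GC and length correction (0.0671). The male-biased median was -0.34 under quantile normalization (0.0518), -0.69 with absent genes set to 0 (0.000143) and -0.62 with no minimum span (0.000212). Genes with groups that did not overlap and a 2-fold difference numbered 493 with a pseudocount of 0.1, where Hjv was -5.63, 584 with loci summed and 212 with at least 80% of a transcript spanned. Leaving out 1 library at a time gave 0 to 214 genes higher, 1 to 67 lower, 0 to 9 lists called and 357 to 822 genes with a 2-fold difference and groups apart. The medians then ranged from -0.80 to -0.62 for fatty acid synthesis, from -0.62 to -0.31 for male-biased genes and from -0.42 to -0.25 for the interferon response. Hjv ranged from -4.66 to -3.08, Hamp from -5.30 to -3.15 and Hamp2 from -3.83 to -1.98, with no value without knockout replicate 2. These genes were not run with quantile normalization, the GC and length correction or other spans, Hamp and Hamp2 have no value with loci up to 1.5 times the midpoint, and the limma settings do not enter their values. With the replicate number as a block, 0 genes passed in either direction, 526 were higher and 358 lower at an unadjusted p under 0.05, and 3 lists were called. The deviations of equally numbered libraries had a correlation of 0.0803 across genes, so the numbers were not read as pairs. The 3 splits of the 4 libraries are too few for a share under 0.05. At an unadjusted p under 0.05, leaving out 1 library gave 125 to 1311 genes higher and 129 to 881 lower, and loci summed gave 217 and 188. The real split gave 871 genes at an unadjusted p under 0.05 and the highest other 195, and it called 3 lists by camera where each of the others called 1, so camera also calls lists where the groups mix the genotypes. Except where an alternative tests fewer genes or libraries, the cause was not tested. Depth limits low transcripts, since loci were assembled only where fragments sufficed. Abundant transcripts were lost too. Of 425 genes at 100 FPKM or more in each of the other libraries, 12 had no locus in knockout replicate 2, Trf among them. The same count was 1 of 379 in wild type replicate 1, 0 of 359 in wild type replicate 2 and 1 of 360 in knockout replicate 1.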

Other observations

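The tests of adipose tissue, of the time of harvest and of the place of the male-biased genes were chosen only after the result was seen, and the GC and length correction was added after the data were seen. In the list for unfolded protein and integrated stress responses, 10 of 17 tested members were below in both knockout libraries and 4 above. The members named here were chosen after their values were seen. The chaperone Hspa5 measured 367 and 330 scaled FPKM in wild type and 165 and 211 in knockout, and Sdf2l1, a partner of chaperones there, 27.1 and 31.8 against 10.9 and 17.8. Atf4, the transcription factor of amino acid stress, measured 40.2 and 33.5 in wild type and 50.3 and 52.3 in knockout. The list's median log2 difference was -0.28 with a camera adjusted p of 0.0744. With values as deposited the list was called lower (adjusted p 0.0265, range 0.00264 to 0.664 over the alternatives; adjusted p = 0.664 with an estimated correlation) with a median of -0.09, so the call depends on the setting. Of its members 0 passed limma when adjusted over the list alone, and 7 were at an unadjusted p under 0.05. The acute phase list had a median of -0.12 and an adjusted p of 0.252, and its median was 0.08 with values as deposited. In it Apcs passed when adjusted over the list alone (adjusted p = 0.00664), while Crp, the C-reactive protein, measured 266 and 258 in wild type and 172 and 154 in knockout.

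Single members of lists that camera did not call passed limma when adjusted over the list alone. They were Ndrg1 in the hypoxia list (2.75 and 2.62 scaled FPKM in wild type, 7.11 and 7.40 in knockout), the apoptosis gene Bax (4.80 and 3.16 against 13.9 and 17.5) and Btg2 (4.86 and 5.70 against 2.11 and 2.61) in the p53 list, and the organic anion transporter Slco1a4 (7.88 and 5.99 against 21.7 and 16.1) in the bile acid list. In the immediate early list Dusp1 and Zfp36, which destabilizes mRNAs (50.0 and 57.8 against 17.5 and 31.1), passed, and so did Plin2 in the fatty acid oxidation list. The camera adjusted p was 0.605 for hypoxia, 0.622 for p53 targets, 0.502 for bile acids and 0.466 for immediate early genes, with medians of 0.11, -0.19, -0.16 and 0.14. For p53 targets, bile acids and immediate early genes the mean had the opposite sign to the median, at 0.06, 0.03 and -0.22, as it had for the clock list (0.04), and camera's direction was down for immediate early and periportal genes although their medians lay above 0. The circadian clock list had a median of -0.01 and an adjusted p of 0.980, the NRF2 and glutathione list -0.15 and 0.237, and xenobiotic metabolism -0.09 and 0.508. Iron-sulfur cluster assembly had a median of 0.23 and an adjusted p of 0.258, cytosolic ribosomal proteins 0.13 and 0.209, pericentral genes -0.16 and 0.262, and periportal genes 0.08 and 0.647. The ribosomal list was called higher under quantile normalization (adjusted p 0.00123, median 0.21, range 0.00123 to 0.936 over the alternatives; adjusted p = 0.664 with an estimated correlation). With values as deposited the medians of the bile acid, clock, NRF2, xenobiotic and pericentral lists turned to 0.03, 0.17, 0.04, 0.11 and 0.01, and under quantile normalization that of the immediate early list turned to -0.04. The only tested cell cycle gene, Pcna, measured 16.5 and 18.4 in wild type and 7.04 and 8.85 in knockout, and the only tested female-biased gene, Cyp17a1, 16.7 and 29.6 against 3.47 and 9.74.

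Lower fatty acid synthesis genes in the knockout libraries may reflect the genotype or a technical difference between the libraries. After a correction for GC content and transcript length the list's median was -0.92 (camera adjusted p 7.47e-07, within a range of 7.47e-07 to 0.650 over the alternatives), which argues against that bias as the whole cause. Fat tissue in the wild type pieces would bring Fabp4, among the most abundant transcripts of fat. However, the wild type excess of Fabp4 was 0.449 times the median excess of the 10 list members below in both knockout libraries, and 6 of the 10 exceeded it. The Fabp4 test replaced a planned one on Adipoq, Cfd, Plin1 and Car3, because Adipoq, Cfd and Plin1 had no value in any library. Car3, abundant in fat and also made by liver, was higher in knockout, but it does not single out fat. Another time of harvest stays open, since 0 of 14 tested clock genes had groups that did not overlap and a 2-fold difference, but only 3 of 7 genes with large daily swings were tested and Dbp, untested, measured 21.3 and 27.2 in wild type and 104 and 45.4 in knockout. Iron level, genotype and feeding state stay open too. Pck1 and Tat, which fasting raises, were lower in both knockout libraries, but they were picked after their values were seen and cannot decide the feeding state. Camera's call of the fatty acid synthesis list is lost with an estimated correlation (adjusted p = 0.650).

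For the male-biased genes, a candidate explanation is DNA carried along with the targeted allele rather than a shared change of the program. Hsd3b5 lies 2.09 Mb from Hjv on chromosome 3, so for this gene a neighboring variant and the loss of Hjv cannot be told apart, as both go with the genotype. C6, Nudt7 and Elovl3, the other members at an unadjusted p under 0.05, lie on chromosomes 15, 8 and 19, and 0 of these 3 lie on chromosome 3, which argues against this explanation for them. The GC and length correction left a median of -0.32 and an adjusted p of 0.0369 (range 0.000143 to 0.650 over the alternatives), with Hsd3b5 at -1.88 and C6 at -1.79, which argues against that bias as the whole cause, though the list's call is lost with an estimated correlation (adjusted p = 0.650 with an estimated correlation). The groups overlapped for 4 of the 10 tested members, among them Slco1a1 (195 and 169 scaled FPKM in wild type, 148 and 183 in knockout) and Cyp7b1 (129 and 165 against 126 and 145). The only tested female-biased gene, Cyp17a1, was lower as well, at 16.7 and 29.6 against 3.47 and 9.74. A change in sex-biased expression with the genotype remains a hypothesis, and 1 female-biased gene is too few to weigh it.

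Knockout replicate 2 differed from knockout replicate 1 more than the wild type libraries did from each other, with an SD of log2 differences of 0.645 against 0.421. The log2 ratio of knockout replicate 2 to knockout replicate 1 had a Spearman correlation of 0.478 with GC content across genes, which are not independent replicates, against 0.263 for the wild type pair, so a GC bias may account for part of the difference. Assembly of transcripts in pieces was tested on the 3209 genes in 1 piece in both knockout libraries, where the SD was still 1.51 times that of the wild type pair (0.633 against 0.419), which argues against pieces as the whole cause. After the GC and length correction that SD was 0.562, against 0.409 for the wild type pair. Relative to wild type replicate 1, the log2 ratio had a Spearman correlation with GC content of 0.553 for knockout replicate 2 and 0.149 for knockout replicate 1. A difference between the animals or their tissue remains open.

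A segment of another strain around the targeted allele may have been carried along by the breeding, which would concentrate large differences near Hjv. Of the 206 tested genes within 20 Mb of Hjv, 9 had groups that did not overlap and a 2-fold difference (4.37%), against 310 of 7717 elsewhere (4.02%). Fisher's exact test, two-sided, gave a p of 0.720. The counts leave open a segment that affects few genes or is shorter than this window, since no narrower window was tested. Of these 9 genes, Bola1, Fmo5, Hsd3b5 and S100a10 lay closest to Hjv, between bases 93555080 and 98630252. Bola1 (96196588 to 96219709) measured 0.654 and 1.29 scaled FPKM in wild type and 2.50 and 17.7 in knockout. Fmo5 measured 119 and 201 against 76.0 and 66.9, and S100a10 183 and 169 against 95.9 and 72.4. Farther away, Tdo2, which breaks down tryptophan, measured 1009 and 887 in wild type and 404 and 542 in knockout.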
